A study of Solanum lycopersicum with 9 samples.

How the data were processed

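Guard cells were isolated from blended leaf epidermis of tomato plants and sequenced as poly A RNA, per the labels' protocols. Groups came from the genotype label: M82, pro and pro∆17 (written pro17 there), with 3 libraries each. The titles of proD17 libraries 2 and 3 name other numbers after the delta sign than the genotype label, which was followed.

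The authors' deposited table gives a signal value for 23028 genes in 9 libraries, headed normalized counts per the file headers and rounded to 2 decimals. Per the submitters' processing notes the tools were cutadapt, STAR 2.4.2a, HTSeq and DESeq2. The genome build and annotation release are not given in the sources used here, nor is the strand setting, so overlapping, antisense and near-identical genes cannot be told apart. The table also holds the authors' log2 fold changes, p-values and adjusted p-values for 3 comparisons, and 2 unnamed columns with group means in 81 rows. Every listed gene has at least 6 reads in some library. One identifier is listed on 2 rows, which were kept apart.

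Within a tolerance of 0.006, 100.0% of values in every library were whole multiples of one step, the value of 1 read, against 0.994% to 1.34% for values unrelated to the step. The step gave whole reads and size factors, and DESeq2's size factors on those reads matched them with a relative gap of at most 2.41e-08. In pro library 1 the step is close to 1. Recovered totals were 14826561 to 20445679 reads per library, and the 10 most abundant genes took 4.35% to 7.28% of them. Ratios and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

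The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2 of the deposited normalized count plus a pseudocount of 1, with all 9 libraries and 3 groups in one fit. Fold changes are on that scale, which understates changes of low genes. Genes passed edgeR's expression filter on the recovered reads (20951 kept, 2077 left out), p-values were adjusted by Benjamini-Hochberg, and the threshold was 0.05. Before the data were examined, edgeR's quasi-likelihood test had been chosen as the main test, with limma for a table from which no counts could be recovered. Although whole reads were recovered, limma on the deposited normalized counts became the main test before any model was fitted, a departure from that choice. EdgeR 4.0.16 with TMM on the recovered reads was added as an alternative after seeing the data. EdgeR with DESeq2 size factors and with upper-quartile factors had been planned as alternatives. DESeq2 1.42.0 on the recovered reads had been chosen as an alternative at the same time as edgeR.

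Each test was first tried on simulated counts with 200 changed genes among 20951. For pro against M82, limma recovered 20.9% of 2-fold, 67.2% of 4-fold and 87.9% of 8-fold changes, with 0.847% false calls among its calls. For proD17 against M82 it recovered 22.4%, 77.6% and 92.4%, with 5.19% false calls. For proD17 against pro it recovered 17.9%, 74.6% and 90.9%, with 8.96% false calls. DESeq2 recovered 41.8%, 82.1% and 95.5% for pro against M82 with 20.2% false calls. Its false calls were 27.4% for proD17 against M82 and 28.9% for proD17 against pro. All these rates are for simulated counts and are not error rates for the real libraries. The median SD over genes on the log2 scale differed between the real groups, at 0.36 in pro, 0.21 in M82 and 0.14 in proD17. Whether the rates hold under such unequal spread was not tested.

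The 23 gene lists were fixed then too, most by words in gene descriptions. The file pairs no descriptions with identifiers, and the reference table used here (assembly SLM_r2.1) matched 0 of them, so 16 lists are void, among them those of mesophyll, vascular and trichome markers. The other 7 lists held 34 loci fixed by identifier from general knowledge, of which 33 were in the table and 31 were tested. That knowledge may include published work on these same samples, so the choice of loci need not be independent of these data. What these loci are was not checked against an annotation. Lists of at least 3 tested loci were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over 3 lists and 3 comparisons. The rule for named genes took, per comparison, the genes highest and lowest in log2 fold change among those that passed, did not overlap between groups, had a mean of at least 1 CPM over the 6 libraries and carried a description. It also took PROCERA, the loci with the smallest p of lists with a camera adjusted p under 0.05 or at least 3 passing loci, and those of the gibberellin metabolism, abscisic acid and NRT1/PTR lists. As no gene carries a description, that condition was dropped and 2 genes per direction were named in place of 7. Loci of lists are given by list, without identifier, except PROCERA and the NRT1/PTR locus.

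Alternatives were other tools, scalings, filters and pseudocounts (0.1 and 5), only the 6 libraries of a comparison, the replicate number as a block, a test against 1.2-fold, genes changed at least 2-fold, and each of the 9 libraries left out in turn. Added after seeing the data were edgeR with TMM (the main test first chosen), limma with TMM scaling and limma with array weights. Also added then were pro library 3 left out with only the groups compared, and libraries of the group outside a comparison left out. Chromosome numbers were read from the identifiers. Shared M82 libraries were simulated 1000 times from residuals within groups, keeping the correlation between genes. Tables were read with Python 3.11.15 and pandas 2.3.3. The authors' fold changes and p-values per gene were not used for the comparisons with M82, for a reason given in the closing observations.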

Results

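Messenger RNA of guard cells, the paired epidermal cells that open and close the stomatal pore, was sequenced from leaves of the tomato cultivar M82 and of 2 lines with altered DELLA activity. DELLA proteins are nuclear repressors of gibberellin responses, and the tomato genome encodes one, PROCERA. The line pro carries a loss of DELLA function and the line pro∆17, called proD17 here, a gain of function. Each of the 3 groups had 3 libraries. The series asks about the part of DELLA in the response of tomato to water shortage. The labels do not say that the libraries of a group came from separate plants, so p-values measure the spread between these samples, which may be technical. Between 14826561 (proD17 library 3) and 20445679 reads (pro library 3) per library were assigned to the 23028 genes listed.

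The proD17 libraries resembled each other most, with a Pearson r across genes of 0.982 to 0.986 between pairs on log2 normalized counts. The M82 pairs gave 0.966 to 0.983 and the pro pairs 0.913 to 0.963. No pair of replicates agreed within sampling noise, the lowest chi-square per degree of freedom being 5.21. The first principal component held 47.6% of the variance and set pro library 3 apart, at 122 against 43.0 for pro library 1, 14.7 for M82 library 3 and values from -35.2 to -26.4 for the other 6 libraries. On the second component, with 20.6% of the variance, the proD17 libraries lay between -42.8 and -36.2, below the other 6.

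**Figure D1:**
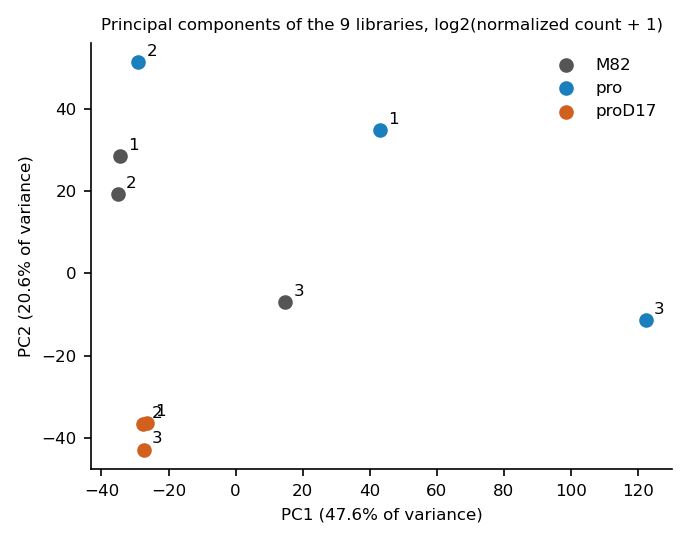
Position of each library on the first principal component (x axis, 47.6% of variance) and the second (y axis, 20.6%), from log2 normalized counts of 20951 genes; points are libraries, numbered by replicate and coloured by group. The proD17 libraries lie together, and pro library 3 lies at 122 on the first component.

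The PROCERA transcript (Solyc11g011260) was read in every library. Its normalized count was 3837 ± 90.8 in M82, 3750 ± 837 in pro and 6187 ± 1094 in proD17 (mean ± SD, n = 3). The 3 proD17 libraries lay above all libraries of the other groups, but no comparison passed limma's test after Benjamini-Hochberg adjustment over all genes. The log2 fold change was -0.06 for pro against M82 (adjusted p = 0.918), 0.68 for proD17 against M82 (adjusted p = 0.325) and 0.73 for proD17 against pro (adjusted p = 0.0772). The last comparison passed with DESeq2 on the recovered reads (adjusted p = 0.0116) and without pro library 2 (adjusted p = 0.0188). The comparison of proD17 with M82 passed when only those 6 libraries were fitted (adjusted p = 0.0434). Over all settings tried, the adjusted p ranged from 0.0110 to 1 in proD17 against M82. In proD17 against pro it ranged from 7.44e-05 to 0.297. The lowest of each came with array weights, whose estimation did not converge. The level of this transcript does not report DELLA protein activity, so it does not check the labels of pro. When the tests were planned, proD17 was taken to carry a transgene of PROCERA, whose reads could count at this locus. Whether they account for the higher count in proD17 was not tested.

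In pro, the line with DELLA loss of function, 44 of 20951 genes passed adjusted p 0.05 against M82 in limma's test, 16 higher and 28 lower in pro. The strongest losses were at Solyc11g028010, which fell from 1291 ± 60.6 in M82 to 1.56 ± 1.4 in pro (log2 fold change -9.18 ± 0.41 SE, adjusted p = 1.84e-05), and at Solyc11g028100, which fell from 3650 ± 271 to 9.97 ± 6.58 (-8.57 ± 0.37, adjusted p = 1.84e-05; mean ± SD, n = 3). The strongest gains were at Solyc06g035940, from 8.70 ± 14.2 to 2542 ± 604 (9.39 ± 1.17, adjusted p = 0.0143), and at Solyc11g030380. The M82 libraries held 3 reads of Solyc11g030380 in all and the pro libraries 2143, a ratio of 680 with a 95% exact binomial interval of 232 to 3300, which covers counting error only (adjusted p = 3.30e-04). The call of Solyc06g035940 was lost under several settings, with adjusted p = 0.0520 in edgeR, 0.0690 when only the 6 libraries compared were fitted, 0.0862 without pro library 1, 0.0982 without M82 library 2 and 0.0543 without M82 library 3, while the calls of the other 3 loci held under every setting tried. With the replicate number as a block, the call of Solyc06g035940 was lost too. The file pairs no name or description with any of the loci named here. Of the 44 genes, 12 carry a chromosome 11 identifier, the chromosome of PROCERA, against 6.93% of the genes tested (Fisher's exact test, adjusted p = 0.00119 over 39 tests of chromosomes and comparisons). Of these 12 loci, 8 were lower in pro and 4 higher.

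**Figure D2:**
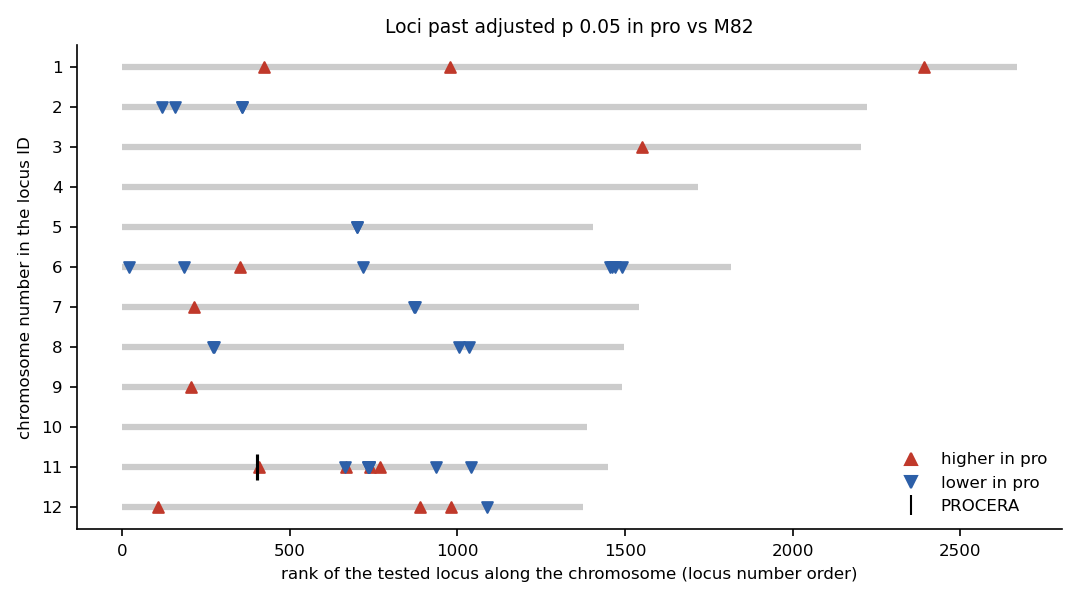
Loci past adjusted p 0.05 in pro against M82, placed on 12 chromosomes (y axis) by their rank among tested loci in identifier order (x axis); upward triangles were higher in pro, downward triangles lower, and the bar marks PROCERA. Chromosome 11 holds 12 of the 44 called genes. Genes with chromosome number 0 are not drawn.

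None of the loci fixed beforehand for hormone lists passed over all genes in pro against M82 with limma or edgeR. The locus of the NRT1/PTR transporter list described further on had a log2 fold change of -1.24 (adjusted p = 0.148) and passed with DESeq2 (adjusted p = 0.00317) and without pro library 2 (adjusted p = 0.00567). Of the 9 gibberellin metabolism loci tested, 3 had an unadjusted p under 0.05 in limma, and, adjusted over the list alone, 1 was higher and 2 were lower. DESeq2 called those 3 over all genes (adjusted p = 4.18e-05, 0.0270 and 0.0485), and limma called the first without pro library 2 (0.0139) or pro library 3 (0.0243) and the second without pro library 2 (0.0329). The list did not move one way in camera (adjusted p = 0.503), its median log2 fold change being 0.29 and its mean -0.15. The 5 loci for gibberellin perception and GRAS regulators, the protein family of DELLA, include PROCERA itself and had a median of -0.30. None passed in either adjustment with limma, where 1 had an unadjusted p under 0.05, or over all genes with edgeR or DESeq2, and the camera adjusted p was 0.118 (0.0383 without pro library 3). The 13 loci for abscisic acid synthesis, turnover and signalling, the hormone path that closes stomata in drying leaves, had a median of 0.81 and were higher in pro by camera with a preset correlation (adjusted p = 8.72e-04), 11 with a positive change. That call was lost with an estimated correlation (adjusted p = 0.369) and without pro library 3 (adjusted p = 0.0805), and no locus passed with limma, over all genes or adjusted over the list alone, 3 having an unadjusted p under 0.05. EdgeR and DESeq2 called 0, and without pro library 2 limma called at least 2 (adjusted p = 0.0256 and 0.0359). As the abscisic acid list pools synthesis, turnover and signalling, its median gives no direction for the path as a whole in any comparison. Pro library 3 held the highest value of the 9 libraries at 11 of 14 abscisic acid and dehydrin loci. The single dehydrin locus, of a family of proteins made in drying tissue, read 35710 normalized counts in pro library 3, 331 in pro library 1 and 7.91 in pro library 2, against 12.6 to 174 in M82.

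**Figure D3:**
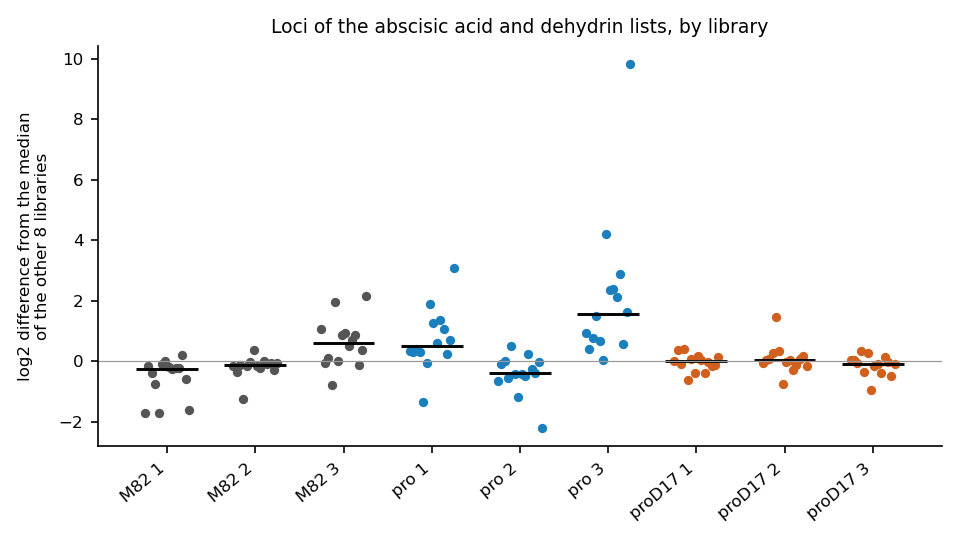
The log2 difference of each of 14 abscisic acid and dehydrin loci from its median in the other 8 libraries (y axis), by library (x axis); points are loci, coloured by group, and bars are medians over loci. The median was 1.56 in pro library 3, 0.61 in M82 library 3, 0.51 in pro library 1 and at most 0.04 in the other libraries.

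The count in pro against M82 depended on the tool and the libraries: DESeq2 on the recovered reads called 184 genes, edgeR 38, and limma without pro library 2 called 766. Smaller counts came without M82 library 1 (27), without M82 library 2 (25), with only the 6 libraries compared (23) and with those libraries less pro library 3 (17). Array weights, which rest on 1 library, gave 9114. The authors' deposited table calls 173 genes.

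In proD17, the line with DELLA gain of function, 25 genes passed against M82 in limma's test, 17 higher and 8 lower in proD17. No M82 or pro library held a read of Solyc11g044455, which stood at 69.3 ± 10 in proD17 (mean ± SD, n = 3), at least 68.8-fold higher against a floor of 3 reads over the M82 libraries (adjusted p = 0.00128). Solyc01g109500 rose from 52.3 ± 26.7 to 812 ± 90.4 (log2 fold change 4.05 ± 0.45 SE, adjusted p = 0.0175). Solyc03g112500 fell from 109 ± 43.9 to 13.3 ± 4.71 (-2.94 ± 0.41, adjusted p = 0.0404) and Solyc10g079980 from 77.0 ± 20.8 to 13.4 ± 4.74 (-2.46 ± 0.31, adjusted p = 0.0304). The call of Solyc11g044455 held under every setting tried, and those of the other 3 loci were lost when single libraries were left out, with adjusted p up to 0.146, 0.197 and 0.184. With the replicate number as a block, the calls of Solyc03g112500 and Solyc10g079980 were lost too. Fewer than 25 genes passed with that block, as given in the closing observations.

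By camera with the preset correlation, the gibberellin lists lay higher in proD17 than in M82. The 5 perception and GRAS loci, PROCERA among them, all had positive changes (median 0.68, the value of PROCERA; camera adjusted p = 5.41e-04, adjusted p = 0.0560 with an estimated correlation, and 0.00396 with fry), and 3, one of them PROCERA, passed adjusted over the list alone. PROCERA is the gene altered in proD17, so its own rise may come with the line and is not independent support for the list. The log2 fold changes of the other loci were 1.11, 1.11, 0.20 and 0.13. Over all genes limma and edgeR called none of the 5 (3 had an unadjusted p under 0.05 in limma), and DESeq2 called 1 (adjusted p = 9.55e-04). The metabolism list had a median of 0.96 (camera adjusted p = 0.0114, adjusted p = 0.0807 with an estimated correlation, and 0.0280 with fry), with 3 of 9 loci higher adjusted over the list alone. Its changes were positive at 6 loci and negative at 3. The list was drawn up to pool different gibberellin oxidases and other enzymes, so its median gives no direction for the pathway as a whole. Over all genes limma and edgeR called none of the 9 (4 had an unadjusted p under 0.05 in limma), and DESeq2 called 1 (adjusted p = 0.00654). With only the 6 libraries compared, the loci of both lists that passed adjusted over the list alone also passed over all genes in limma, the metabolism loci with adjusted p = 0.0147, 0.0182 and 0.0350. Without pro library 3, 2 of these metabolism loci passed (0.0298 and 0.0308), and 1 perception locus passed without pro library 2 (0.0264) or 3 (0.0218), another without pro library 2 (0.0233). Of the 3 metabolism loci, one had 3 reads in M82 and 69 in proD17, a ratio of 23.0 with a 95% exact interval of 7.53 to 114. The abscisic acid list had a median of 0.01 (camera adjusted p = 0.472), with 0 of 13 loci passing in limma, edgeR or DESeq2 and 1 with an unadjusted p under 0.05 in limma, which passed with only the 6 libraries compared (adjusted p = 0.0150). The single locus of the list of NRT1/PTR transporters, the family of the abscisic acid importer AIT1, Solyc05g006990, stood at 592 ± 66.6 in M82 and 1386 ± 99.9 in proD17 (log2 fold change 1.23 ± 0.24 SE) and did not pass over all genes (adjusted p = 0.136). It passed with DESeq2 (adjusted p = 9.87e-04), with only the 6 libraries compared (adjusted p = 0.00381), and without pro library 2 (0.0216) or pro library 3 (0.0189).

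All groups share one estimate of the spread in this fit, and the pro libraries vary most: the median SD over genes on the log2 scale was 0.36 in pro, 0.21 in M82 and 0.14 in proD17. Fitted on the M82 and proD17 libraries alone, limma called 436 genes, all 25 among them, and without pro library 1, 2 or 3 it called 16, 88 and 199. Without M82 library 2 or 3 it called 2 each, and without proD17 library 1, 2 or 3 it called 3, 5 and 1. DESeq2 called 314 and edgeR 17, and limma with a pseudocount of 5 called 41. Array weights, whose estimation did not converge, gave 1624, and 308 genes are called in the authors' deposited table.

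Between the lines with opposite DELLA activity (proD17 against pro), 712 of 20951 genes passed, 459 higher and 253 lower in proD17. This was the highest count of the 3 comparisons with all 9 libraries in limma's fit, but with only the 6 libraries of each comparison 273 genes passed here and 436 in proD17 against M82. The NRT1/PTR locus Solyc05g006990 rose from 261 ± 99.8 in pro to 1386 ± 99.9 in proD17 (log2 fold change 2.47 ± 0.24 SE, adjusted p = 0.00148), with M82 between them at 592 ± 66.6, and this call held under every setting tried (adjusted p up to 0.0141). The locus was fixed from general knowledge, so its choice need not be independent of these data. In the gibberellin metabolism list, 2 loci rose and 1 fell. One rose from 180 ± 92.2 to 1767 ± 74.9 (3.45 ± 0.39, adjusted p = 0.00271) and another from 29.8 ± 14.2 to 302 ± 81.9 (3.36 ± 0.41, adjusted p = 0.00394), while the third fell from 120 ± 56.0 to 23.5 ± 7.01 (-2.20 ± 0.48, adjusted p = 0.0425), a call lost without any one library other than M82 library 3 and pro library 2 (adjusted p from 0.0635 to 0.166). Adjusted over the list alone, 4 loci rose and 2 fell. The list as a whole had a camera adjusted p of 0.0607 and a median of 1.12, and camera passed without M82 library 2 or 3, pro library 3 or proD17 library 1 (adjusted p as low as 0.0483) but not with an estimated correlation (adjusted p = 0.174). Changes in either direction gave an adjusted p of 1.28e-04 in fry's mixed test.

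Of the 5 perception and GRAS loci, 2 rose, from 199 ± 63.1 to 632 ± 58.1 (1.71 ± 0.22, adjusted p = 0.00521) and from 133 ± 64.4 to 422 ± 19.7 (1.79 ± 0.34, adjusted p = 0.0264). The second call was lost without M82 library 2 (adjusted p = 0.0540), pro library 1 (0.0609) and each proD17 library (0.118, 0.104 and 0.107). Adjusted over the list alone, 3 rose, the third being PROCERA. The list was higher in proD17 by camera (adjusted p = 0.00164), a call lost with an estimated correlation (adjusted p = 0.0560) and kept with fry (adjusted p = 0.00238). PROCERA counts in these tests too, although it is the gene altered in these lines. The abscisic acid list was lower in proD17 by camera (median -0.41, adjusted p = 0.0431), without a passing locus in either adjustment with limma (2 had an unadjusted p under 0.05) or over all genes with edgeR. DESeq2 called 2 loci of the list lower (adjusted p = 0.00265 and 0.0175), the first of which also passed in limma without pro library 2 (0.00417). The camera call was lost with an estimated correlation (adjusted p = 0.576) and without pro library 3 (adjusted p = 0.585), the library in which those loci stood highest, and also without pro library 1 (0.0556), proD17 library 1 (0.0577) or proD17 library 3 (0.0653). The dehydrin locus had a log2 fold change of -3.58 (adjusted p = 0.468). The guard cell ion transport locus (0.17, adjusted p = 0.626) and the stomatal lineage locus (0.11, adjusted p = 0.723) did not pass.

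**Figure D4:**
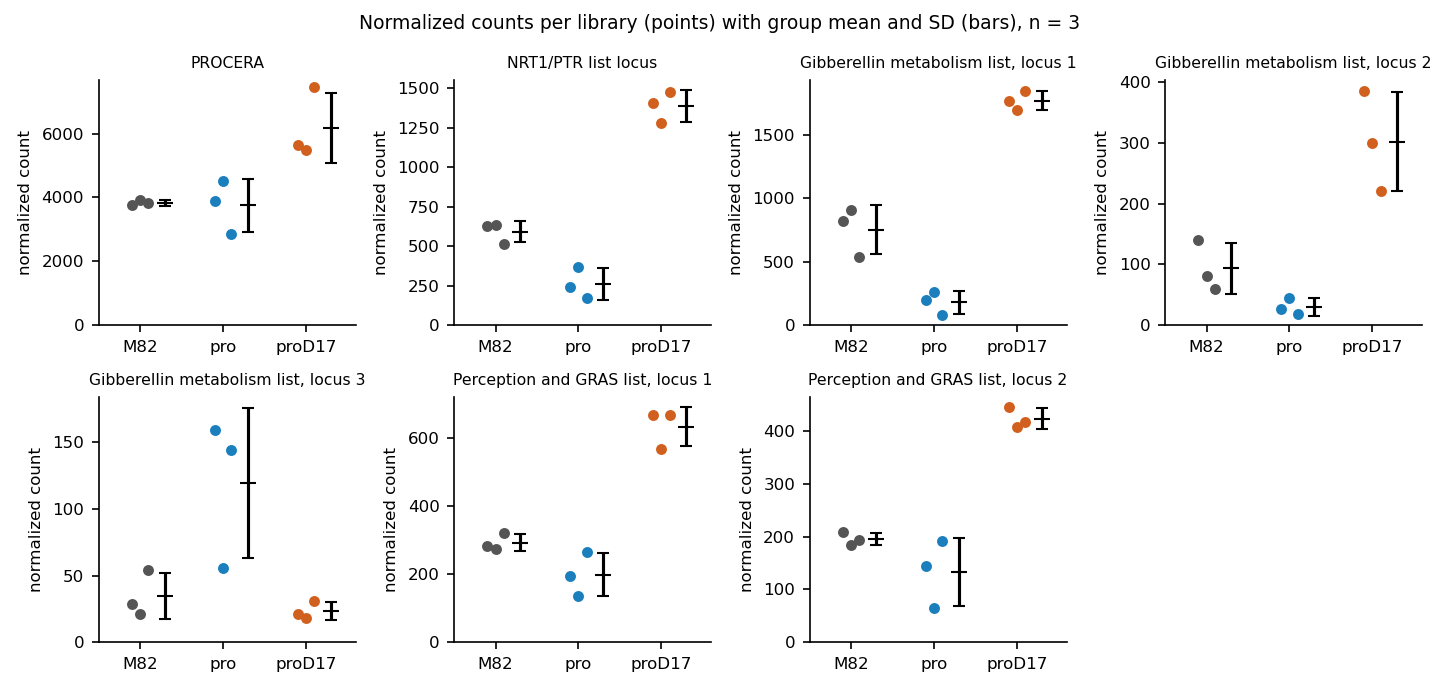
Normalized counts (y axes, linear from 0) per library by group (x axes) at PROCERA, the NRT1/PTR locus, the 3 called gibberellin metabolism loci and the 2 called perception and GRAS loci; points are libraries and bars the mean and SD (n = 3). The NRT1/PTR locus has group means of 592 in M82, 261 in pro and 1386 in proD17, and its groups do not overlap.

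The largest changes between the mutants were at loci named above: Solyc11g028010 (log2 fold change 9.12) and Solyc11g028100 (8.53) were higher in proD17, and Solyc11g030380 was lower (-8.40). At Solyc00g107055, the pro libraries held 868 reads and the proD17 libraries 2, a ratio of 414 with a 95% exact interval of 114 to 3424 (adjusted p = 8.72e-05). At the first 3 loci proD17 was close to M82. DESeq2 called 1813 genes between the mutants and 1799 are called in the authors' deposited table, while limma gave 273 with the 6 libraries alone, 269 in the test against 1.2-fold and 12552 with the array weights. Without single libraries the count was 3196 (pro library 2), 1130 (pro library 3), 329 (pro library 1), 374 (M82 library 2), and 161, 173 and 174 (proD17 libraries 1, 2 and 3).

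Among genes passing against M82 in both lines, 1 changed in opposite directions in pro and proD17 and 1 in the same direction. These are differences between lines, and line background was not separated from DELLA function. Solyc02g065220 fell from 377 ± 25.7 in M82 to 156 ± 24.9 in pro and rose to 1054 ± 85.6 in proD17 (mean ± SD, n = 3). Solyc12g087830 rose from 111 ± 49.3 to 1392 ± 213 in pro and 1383 ± 146 in proD17. Both are named because the counts are 1, after their values were seen. Independent lists of these sizes would share 0.029 genes in opposite and 0.024 in the same direction, and the overlap had p = 0.00125 in Fisher's exact test. The M82 libraries are shared, so part of an overlap in the same direction may come from them, and 3 libraries are too few to split. The opposite count was 29 with DESeq2, 23 without pro library 2 and 4 without pro library 3, and 0 without any single M82 or proD17 library. Across genes, which are not independent replicates, the fold changes of pro and proD17 against M82 had a Pearson r of 0.0583 and a Spearman rho of 0.0422. Unchanged groups sharing the M82 libraries gave a median r of 0.463 in 1000 simulations (95% range -0.19 to 0.91). The covariance was 0.0135 against a simulated median of 0.0335 (-0.0189 to 0.253). The correlation was 0.321 without M82 library 3.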

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

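The test with edgeR and TMM had been the main test first chosen, and it came back as an alternative after the data were seen. Limma with TMM scaling, array weights, pro library 3 left out with only the 2 groups, and libraries outside a comparison left out were chosen after seeing the data. Counts below are for pro against M82, proD17 against M82 and proD17 against pro, where limma gave 44, 25 and 712. Scaling and filters kept each count within 1.5 times. DESeq2 gave 184, 314 and 1813, and only the 6 libraries compared 23, 436 and 273. A pseudocount of 5 gave 41 in proD17 against M82, the 1.2-fold test 269 in proD17 against pro, and pro library 3 left out with only the 2 groups 17 in pro against M82. Array weights gave 9114, 1624 and 12552, but their estimation stopped before converging. It set pro library 1 at 41.0 against 0.159 and 0.108 for the other pro libraries, so the counts 9114 and 12552 rest on 1 library. In M82 and proD17 the weights ran from 0.413 to 1.92, from the same estimation. None of these counts is used as evidence. Leaving out 1 library gave 25 to 766, 1 to 199 and 161 to 3196. The cause was not tested.

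With the replicate number as a block the counts were 34, 12 and 890, holding 33 of the 44, 11 of the 25 and 650 of the 712 genes. Among the named genes, Solyc06g035940 in pro against M82 (adjusted p = 0.0588) and Solyc03g112500 (0.0753) and Solyc10g079980 (0.0869) in proD17 against M82 no longer passed. Of 9 same-numbered pairs across groups, 6 deviated together with a correlation above 0.1 (range 0.0219 to 0.523), including the 3 pairs of M82 and pro (0.133, 0.503 and 0.523). All 9 were positive, so same-numbered libraries may share a source of variation. Most pairs with different numbers were negative, down to -0.555 for M82 library 3 and pro library 2. The values were centred within each group, which forces such pairs negative on balance once same-numbered pairs are positive. They add no separate evidence. The numbers were not taken as pairs, because the labels do not pair them and not all 9 exceeded 0.1. Also, M82 library 1 correlated better with pro library 2 (0.259). The values do not settle this choice.

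PROCERA in pro against M82 changed sign with array weights (0.0070) and with pro library 3 left out with only the 2 groups (0.13), and ranged from -0.20 to 0.13 without single libraries. In proD17 against M82 it passed with only the 6 libraries (0.68) and array weights (0.70). In proD17 against pro it passed with DESeq2 (0.72) and array weights (0.69), and ranged from 0.55 to 0.88. The NRT1/PTR locus passed in pro against M82 with DESeq2 (-1.18) and array weights (-1.34), ranging from -1.52 to -0.98. In proD17 against M82 it passed with DESeq2 (1.23), only the 6 libraries (1.23) and array weights (1.17), ranging from 1.13 to 1.29. The dehydrin locus (3.38, -0.20 and -3.58 in limma) moved most with DESeq2 (7.32, -0.96 and -8.29) and edgeR with TMM (7.31, -0.97 and -8.28). DESeq2 gave it no adjusted p and edgeR did not call it. It passed with array weights in pro against M82 and proD17 against pro (3.15, 0.055 and -3.10), and ranged from -1.07 to 0.77 in proD17 against M82 and from -6.45 to -0.46 in proD17 against pro. The ion transport locus in pro against M82 changed sign with edgeR (0.0024 with TMM, 2.48e-04 with DESeq2 factors), array weights (0.23) and pro library 3 left out (0.058), ranging from -0.13 to 0.058. With array weights it was -0.068 in proD17 against pro, and the stomatal lineage locus 0.31 in pro against M82 and -0.10 in proD17 against pro. That locus ranged from -0.044 to 0.25 and from -0.063 to 0.23.

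List adjusted p-values moved as follows. With an estimated correlation, gibberellin metabolism in proD17 against M82 gave 0.0807, the perception list 0.0560 in both proD17 comparisons, and the abscisic acid list 0.369 in pro against M82 and 0.576 in proD17 against pro. With fry the abscisic acid list gave 0.330 and 0.372, and metabolism in proD17 against pro 0.00896. Without single libraries camera gave 0.0483 to 0.0852 for metabolism in proD17 against pro, 0.0383 to 0.466 for the perception list in pro against M82, and for the abscisic acid list 1.48e-05 to 0.0805, 0.0761 to 0.852 and 5.11e-04 to 0.585. Genes opposite in both mutants numbered 29 with DESeq2, 2 with a pseudocount of 5, 479 with array weights and 0 to 23 without single libraries. The correlation of fold changes ranged from -0.0199 to 0.321.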

Other observations

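The tests of pro library 3, chromosome 11, near neighbours and the deposited columns, and the position of M82, were chosen after the results were seen. The splits of the samples were planned.

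Of the 712 genes called in proD17 against pro, the M82 mean lay between the group means at 665 (93.4%), with a median position of 0.45 on a scale from pro at 0 to proD17 at 1. At 291 of them (40.9%) every M82 library lay between all pro and all proD17 libraries, 203 rising and 88 falling from pro to proD17. The share with the M82 mean between was 92.5% for edgeR's calls and 94.4% without pro library 3. For DESeq2 it was 92.1% of the 1774 calls that passed the expression filter. The share with every M82 library between was 41.9% with edgeR, 21.9% of those DESeq2 calls and 50% without pro library 3. These genes were chosen for a difference between the mutants, which by itself tends to place another group between them, so the shares are given as values and do not test an effect graded with DELLA activity.

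Some loci were read in one line and near silent in the others. With at most 3 reads in each silent library and at least 10 in each of the rest, 11 genes were silent in pro and 6 were read only in pro, 1 was silent in proD17 and 6 were read only in proD17, and 0 were either for M82. The 81 other ways to pick 3 of the 9 libraries gave at most 4 such genes and a median of 0. Of the pro genes, 5 silent and 2 read only there carry chromosome 11 identifiers.

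The chromosome 11 loci called in pro against M82 may mark a chromosome segment linked to PROCERA that came with the pro allele. Their identifiers ran from Solyc11g011340 to Solyc11g066150, all numbered above PROCERA (Solyc11g011260). The test below covers the whole chromosome and cannot place such a segment. Chromosome 11 held 12 of 44 called genes (Fisher's exact test, adjusted p = 0.00119), and 1 of 25 in proD17 against M82 (adjusted p = 1). The excess held with edgeR (11 of 38), DESeq2 (26 of 184) and without pro library 3 (13 of 45). Loss of DELLA activity as the cause cannot be told apart from this, since a gain of function need not move a gene that the loss moves: the median change in proD17, signed against that in pro, was -0.0531, and it was -0.0526 at the 32 called loci off chromosome 11, so it does not separate these explanations. In proD17, 9 of the 12 chromosome 11 loci lay within 0.5 log2 of M82, against 13 of the 32 off it. In pro, 7 of the 12 were near silent (at most 20 normalized counts, with an M82 mean above 20), against 6 of the 32. As a gain of function need not move these genes, the counts do not decide between the explanations. Neither a sequence variant that keeps reads from mapping nor a missing gene was tested. 

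Across chromosomes, called loci of pro against M82 also lay near each other in a permutation test, with 12 pairs at most 20 tested loci apart against a random median of 1 (p = 1e-04, the smallest that 10000 draws can give), and 6 pairs off chromosome 11 (permutation p = 4e-04). In proD17 against pro there were 358 pairs against 348 (permutation p = 0.2).

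The abscisic acid and dehydrin loci stood high in pro library 3, with a median log2 excess of 1.56 over the other libraries. Unequal depth is argued against, since even before scaling the reads of pro library 3 exceeded the median of the other libraries by only 0.10 log2. A sample of M82 or proD17 under a pro label is argued against too: at 6 loci near silent in the other pro libraries, pro library 3 reached at most 0.766% of the M82 mean. A response to abscisic acid or drying in that library stays open and was not decided: the 14 loci lay above 100% of 10000 expression-matched random lists, but they did so in M82 library 3 and pro library 1 too, and random lists leave out that such loci vary together. Pro library 3, pro library 1 and M82 library 3 also lie highest on the first principal component (122, 43.0 and 14.7). The excess thus follows an axis that crosses the genotypes and is not particular to pro library 3. Cells of other types were not tested, as no marker list had loci.

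The authors' deposited fold changes in the comparisons with M82 often disagree with the normalized counts in their own rows. The gap was over 0.15 log2 at 58.4% of the 173 called genes in pro against M82 and 45.8% of the 308 in proD17 against M82. In proD17 against pro, with 1799 called, it was found at 0. Only called genes with both group means above 0 could be checked, which were 167, 306 and 1775. A candidate explanation is a list sorted by fold change laid over rows sorted by locus: in locus order, 95.3% of steps among called genes over 2-fold did not rise in size, against 49.1% in proD17 against pro. Sorted row ratios matched sorted deposited values within 0.1 at 120 of 122 and 170 of 170 genes. DESeq2 on the recovered reads called 170 of the 173 and 308 of the 308, but the deposited adjusted p differed from its value over 10-fold at 89 of the 170 and 99 of the 308 genes, against 20 of 1788 in proD17 against pro. In the p-value column of proD17 against M82, 1 cell holds a value above 1, which is 2 to the power of the fold change in its row. No biological explanation was tested.

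With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In pro against M82, 2 splits gave at least the real 44 genes, and the highest other split, M82 libraries 1 and 2 with pro library 2, gave 3039. That count points to a structure of the samples that crosses the genotypes: the other side holds M82 library 3 and pro libraries 1 and 3, which also lie highest on the first principal component. In proD17 against M82 and in proD17 against pro, 1 split (the real one, with 25 and 712 genes) gave as many, and the highest of the other splits gave 0 in each.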
